A study of Mus musculus with 24 samples.

How the data were processed

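Messenger RNA of single cells was measured with droplet 3' libraries in 16 bone marrow samples of the mouse leukaemia model, 8 in the nilotinib time course and 8 in the 14-day experiment, with 2 libraries in each of the 8 groups. Another 8 entries describe antibody libraries and have no files of their own; their counts are in the matrices of the 14-day experiment, with 6 surface antibodies and 2 hashtags (antibody barcodes for pooled samples) per library. The protocol of the 14-day experiment states 4 replicates per group. Nothing in the labels says whether the libraries of a group are separate pools of animals, so the p-values measure only the spread between these samples.

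The authors aligned reads to mm10 and counted them with Cell Ranger. The values are counts per the file headers: raw UMI counts, with no normalization, per gene and cell. Per the file headers the time course was made with version 3.1.0 and 31053 genes and the 14-day experiment with cellranger-7.0.0 and 32285 genes plus 8 antibody tags, and the barcodes are those the authors kept as cells. The human BCR-ABL transgene is not in that annotation. Gene positions were taken from the reference annotation by identifier.

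Cells with at least 500 genes and at most 10% of UMIs from mitochondria-encoded genes were kept, 40991 of 48185 barcodes in the time course and 85287 of 104900 in the 14-day experiment. Median UMIs per cell kept were 8047 to 23456 and 3259 to 8630. One library of the combination group kept 55.2% of its barcodes. Cells called doublets by scrublet were at most 0.611% of a library, so that call has hardly worked and leaving those cells out tests little. UMIs were summed over the cells of a library, and the library was the unit of every test (n = 2 per group); cells were not treated as replicates. Intervals and floors cover counting error only.

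Genes were tested with edgeR 4.0.16 quasi-likelihood fits in R 4.3.3, with filterByExpr, TMM factors and all 4 groups of an experiment in 1 fit (4 residual degrees of freedom), so that all groups share the estimate of spread. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. Gene lists of energy metabolism, signalling, cell types, other cells and RNA quality, 37 in all, were tested with camera of limma 3.58.1 (inter-gene correlation 0.01) and adjusted over the lists of a comparison; a list needed 5 measured members. With the correlation between genes estimated from the data no list passed in any comparison, and those values stand beside each list. The comparisons were nilotinib against vehicle at 2 days and at 2 weeks, the difference of these, vehicle at 2 weeks against vehicle at 2 days, TKI, HIFi and both against vehicle at 14 days, both against TKI, and the departure of both from the sum of TKI and HIFi.

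The named genes were, for each treatment comparison, the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 20 CPM (the count of a gene scaled to the library total), groups that do not overlap (a chance of 0.333 with 2 against 2 libraries) and an established symbol; up to 4 members with the smallest adjusted p of each described list; and Kit, Ly6a, Flt3, Bcr and Abl1. Some genes that met this rule are left out of the text. Groups, comparisons, lists, the naming rule, the filters and most of the alternatives were set before the data were examined.

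Cells of each experiment were clustered with scanpy 1.11.5 (2000 variable genes, centring within each library, 30 principal components, Leiden resolution 0.6 with igraph 0.11.9). A cluster took the class of a marker list when at least 3 of its markers were raised by 0.5 on the log2 scale and at least 1 was among its top 10 genes; other clusters stayed unnamed. Shares of classes were compared by an exact permutation test, two-sided. HSC-like cells were also summed and tested alone, in libraries with at least 50 of them. Surface antibodies were expressed as the centred log ratio within a cell, with the median per library.

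Alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, no cell filter, no doublets, a block for the library number (not for vehicle over time, whose numbers differ), only the 2 groups compared, each cell thinned to 2000 UMIs, each library left out in turn, clustering at resolution 1.0 or without centring, and in the 14-day experiment hashtags as samples (in edgeR, and in limma voom with duplicateCorrelation, whose consensus correlation was 0.776). Runs without clusters of mature cells, with a term for libraries above 1% of counts in Gm42418, in cells outside HSC-like clusters, in the largest HSC-like cluster, and HSC-like lists without vehicle replicate 3 at 2 weeks were added after the data were seen. The fits were tested on simulated data with the spread of each experiment. Of 100 genes changed 2-fold 100% were found at 2 days and at 2 weeks and 1% at 14 days. Of 100 changed 1.5-fold it was 87%, 89% and 0%. These rates hold for the changed genes and are not the power over all genes. Of genes called 13 of 202, 7 of 197 and 0 of 1 had not been changed. A simulated shift of -0.25 in the respiratory chain list gave adjusted p = 5.72e-19, 6.92e-20 and 0.00278, and no other list was called. Real list calls ended with an estimated correlation, so this says little on false list calls. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.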

Results

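Single-cell RNA was measured in bone marrow cells sorted as lineage-negative, FLT3-negative, c-Kit-positive and Sca-1-positive, the gate that holds blood stem cells and early progenitors. The mice carried the inducible SCL-tTA/BCR-ABL transgene pair, in which withdrawal of tetracycline switches on the leukaemia gene BCR-ABL in stem cells. A first experiment, here called the time course, had 4 groups of 2 libraries: vehicle and nilotinib at 2 days, and vehicle and nilotinib at 2 weeks. Nilotinib blocks the BCR-ABL tyrosine kinase and was given at 50 mg per kg daily by gavage. A second experiment, at 14 days, had 4 groups of 2 libraries: vehicle, TKI (nilotinib per the protocol), HIFi, and TKI with HIFi. The labels neither spell out HIFi nor name a compound for it. The human BCR-ABL transcript itself is not counted against the mouse genome. In the time course 1637 to 7620 cells per library passed the cell filter, with 43588615 to 90134878 UMIs (counted molecules) per library. In the 14-day experiment it was 7222 to 14358 cells and 50284242 to 132608241 UMIs.

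Nilotinib against vehicle at 2 days asks what the cells express soon after the kinase is blocked. Genes of the interferon response, of antigen presentation and of megakaryocyte and red-cell progenitors were higher, and the feedback genes Socs3 and Id1, genes of mitosis and genes of mitochondrial energy supply were lower. In edgeR 181 of 14404 genes changed, 114 up and 67 down. Car1, a carbonic anhydrase of red-cell precursors, rose by 2.29 ± 0.35 (SE) on the log2 scale, from 37.9 ± 4.16 to 186 ± 13.2 CPM (the count scaled to the library total; SD, n = 2 libraries, adjusted p = 0.0274). Socs3, a brake on cytokine signalling that STAT factors switch on, fell by 1.34 ± 0.18, from 32.0 ± 0.608 to 12.7 ± 3.57 CPM (adjusted p = 0.0229).

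Among the largest rises at 2 days of genes with a mean of at least 20 CPM, Igtp, an interferon-induced GTPase, rose by 0.90 ± 0.10 (SE, log2, adjusted p = 0.0118), and the class I antigen-presenting gene H2-Q7 by 0.88. The class II gene H2-Ab1 rose by 1.06. The haem-pathway reductase Blvrb rose by 0.98, the immediate early transcription factor Egr1 by 0.94 and the ribonuclease Rnase6 by 0.91. On the other side Prtn3, a granule protease of myeloid progenitors, fell by 0.79 ± 0.10 (adjusted p = 0.0153). The inhibitory antibody receptor Fcgr2b fell by 0.92, the interferon-inducible membrane gene Ifitm1 by 1.06, the secreted epidermal gene Dmkn by 1.15 and the endoplasmic reticulum chaperone Fkbp11 by 0.79. The antibody chains Igkc and Ighg1 were far lower. Igkc went from 452 ± 277 to 1.09 ± 0.889 CPM (adjusted p = 0.0498). Ighg1 had 33412 UMIs in the vehicle pair and 1 in the nilotinib pair, 29400-fold lower with an exact Poisson 95% interval of 5276 to 1161000. The list of mature B and plasma cells did not go with these chains: of 13 genes 1 fell and 8 were higher (median 0.84, mean 0.13, adjusted p = 0.293), with a list call upward without vehicle replicate 1 (0.00653) or nilotinib replicate 1 (0.0351).

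The signalling and cell type lists moved as groups at 2 days. Of 39 measured interferon genes 7 rose and none fell (22 and 0 adjusted over the list alone), with a median log2 change of 0.50 (camera adjusted p = 1.05e-22, and adjusted p = 0.309 with an estimated correlation). Iigp1, an interferon-induced GTPase, rose by 2.93 ± 0.29, and Gbp2, a guanylate-binding protein, by 0.91. All 7 class II antigen-presentation genes were higher (median 1.55; 2 rose, and 7 adjusted over the list alone, adjusted p = 5.23e-11, and adjusted p = 0.305 with an estimated correlation); H2-DMb1 rose by 0.56, and Ciita, their master activator, stood at 1.55 (adjusted p = 0.058). Of 26 genes of megakaryocyte-erythroid progenitors 10 rose (21 adjusted over the list alone, median 0.86, adjusted p = 2.59e-26, and adjusted p = 0.305 with an estimated correlation), among them the red-cell transcription factor Klf1 by 1.82 ± 0.24, the blood-group gene Ermap by 2.58 and the platelet receptor gene Gp9 by 0.79.

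Of 30 stem cell genes 27 were higher at 2 days, with none past the test over all genes except 1 that fell, Ifitm1 (1 up and 1 down adjusted over the list alone, median 0.36, adjusted p = 7.58e-05, and adjusted p = 0.443 with an estimated correlation). Mllt3, a regulator of stem cell self-renewal, stood at 0.54 (adjusted p = 0.056) and the transcription factor Meis1 at 0.38. The myeloid progenitor list was lower (25 measured, 1 fell; 1 up and 4 down adjusted over the list alone, median -0.17, adjusted p = 0.0159, and adjusted p = 0.443 with an estimated correlation). Its call ended without vehicle replicate 2 (adjusted p = 0.145), without nilotinib replicate 1 (0.0761) or with each cell thinned to 2000 UMIs (0.069). Of 36 genes of G2 and mitosis 4 fell (26 adjusted over the list alone, median -0.29, adjusted p = 4.84e-16, and adjusted p = 0.417 with an estimated correlation): Cdca3 by 0.49, Ccnb2, a mitotic cyclin, by 0.50, the spindle gene Tacc3 by 0.41 and the centromere histone Cenpa by 0.42. Of 15 STAT5 and cytokine feedback genes 3 fell (4 adjusted over the list alone, median -0.19, adjusted p = 0.000691, and adjusted p = 0.417 with an estimated correlation): Socs3, the differentiation inhibitor Id1 by 1.30 ± 0.16 and the survival kinase Pim1 by 0.48.

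Energy metabolism was lower by small amounts in many genes at once. All 75 measured nuclear-encoded respiratory chain genes, which build the complexes of oxidative phosphorylation, had lower values (median -0.22, adjusted p = 4.84e-16, and adjusted p = 0.431 with an estimated correlation). None passed on its own in edgeR, over all genes or adjusted over the list alone; 49 were lower at an unadjusted p under 0.05 and 22 fell in DESeq2. Uqcrq of complex III stood at -0.42 ± 0.09 (adjusted p = 0.0578). The 13 mitochondria-encoded genes had a median of -0.13 (adjusted p = 0.0814; 0.0384 without vehicle replicate 2), with mt-Cytb at -0.28. Of 75 mitochondrial ribosome genes 74 were lower (1 fell, and 33 adjusted over the list alone, median -0.25, adjusted p = 1.88e-18, and adjusted p = 0.431 with an estimated correlation), and Mrpl44 fell by 0.37. In the TCA cycle and pyruvate entry 23 of 25 genes were lower (none fell over all genes, 15 at an unadjusted p under 0.05, 8 in DESeq2 and 9 adjusted over the list alone, median -0.20, adjusted p = 2.03e-07, and adjusted p = 0.417 with an estimated correlation). Pdha1 of pyruvate dehydrogenase stood at -0.31.

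Of 25 glycolysis genes 1 fell at 2 days, Gapdh, by 0.55 ± 0.09, from 2804 ± 19.4 to 1915 ± 206 CPM (adjusted p = 0.0337). The list had a median of -0.15 (2 up and 10 down adjusted over the list alone, adjusted p = 0.0238, and adjusted p = 0.443 with an estimated correlation). That call ended without nilotinib replicate 1 (adjusted p = 0.346) and with thinned cells (0.0969). Ldha, which makes lactate, stood at -0.42. The 27 genes of fatty acid oxidation had a median of -0.17 (none passed over all genes, with 2 higher and 14 lower at an unadjusted p under 0.05 and 10 fallen in DESeq2; 1 up and 13 down adjusted over the list alone, adjusted p = 7.03e-05, and adjusted p = 0.305 with an estimated correlation), and Cpt1a, which brings fatty acids into mitochondria, stood at -0.65. Targets of HIF, the oxygen-sensing factor, did not pass as a list (29 measured, median -0.08, adjusted p = 0.0596; 0.0266 without vehicle replicate 1, 0.0403 without vehicle replicate 2 and 0.0364 without nilotinib replicate 2). Cholesterol synthesis went the other way: 3 of 22 genes rose, Srebf2, its master regulator, by 0.42, the sterol carrier Stard4 by 0.48 and the cyclase Lss by 0.77 (3 adjusted over the list alone, median 0.24, adjusted p = 0.00023, and adjusted p = 0.443 with an estimated correlation).

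Genes that define the gate or the disease did not pass the test at 2 days: Kit stood at 0.47 ± 0.13 (adjusted p = 0.11), Ly6a at 0.17, Flt3 at -0.01, mouse Bcr at 0.19 and mouse Abl1 at 0.17. The gene count rested on both libraries of each group, with 1 gene left without vehicle replicate 1 or 2 and 0 without nilotinib replicate 1 or 2 (edgeR; the remaining library is assumed to vary like the other groups). With a block for the replicate number it was 527, in DESeq2 933, and with thinned cells 51.

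At 2 weeks of nilotinib the same question was asked after longer treatment. Genes of stem cells, of the interferon response and of megakaryocyte-erythroid progenitors were higher. Genes of myeloid progenitors and mast cells, of the respiratory chain and TCA cycle, of glycolysis and of amino acid transport were lower. In edgeR 3324 of 14404 genes changed, 1678 up and 1646 down. Prtn3 fell by 1.38 ± 0.10 (SE, log2), from 2303 ± 111 to 884 ± 91.4 CPM (SD, n = 2, adjusted p = 0.00048). Mllt3 rose by 1.35 ± 0.11, from 7.08 ± 0.0129 to 18.0 ± 1.17 CPM (adjusted p = 0.00095).

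Among genes with a mean of at least 20 CPM the largest rises at 2 weeks were in the heat-shock genes Hspa1b, by 3.0 ± 0.49 (adjusted p = 0.00611), and Hspa1a, by 2.93 ± 0.57. Pf4, a platelet chemokine, rose by 2.12 ± 0.31, the interferon-induced genes Ifi27l2a by 1.78 and Rtp4 by 1.51, and the stem cell gene Gimap6 by 1.33, from 19.0 ± 6.55 to 48.3 ± 1.4 CPM. Car1 rose by 1.25 (adjusted p = 0.032), a call that ended without vehicle replicate 3 (1.14) or 4 (1.36) and without nilotinib replicate 3 (0.40). The antibody chain Ighm rose by 2.20, ended without vehicle replicate 3 (1.61) or nilotinib replicate 3 (1.49). Mt1, a metal-binding protein, fell by 2.88 ± 0.22, from 375 ± 93.8 to 51.0 ± 13.7 CPM. The monocyte chemokine receptor Ccr2 fell by 2.63, the myeloid gene Ms4a3 by 2.50, the mast cell genes Fcer1a by 2.46 and Cma1 by 2.22, the receptor gene Mrgpra2b by 2.23, and the granule protease Ctsg by 2.06, from 1800 ± 523 to 433 ± 35.3 CPM. Ighg1 had 15001 UMIs in the vehicle pair and 0 in the nilotinib pair, at least 5492-fold lower against 3 counts over the group. Immediate early and dissociation-stress genes, which respond to cell handling, were higher at 2 days (24 measured, 2 rose; 12 up and 1 down adjusted over the list alone, median 0.51, adjusted p = 2.89e-06, and adjusted p = 0.431 with an estimated correlation). At 2 weeks 4 of them rose and 2 fell and the list did not pass (median 0.33, adjusted p = 0.134), though it did without vehicle replicate 3 (0.0141) or nilotinib replicate 3 (9.39e-06) and with the replicate block (0.0213).

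Of 30 stem cell genes 24 rose at 2 weeks and 1, Ifitm1, fell (25 and 1 adjusted over the list alone, median 1.01, adjusted p = 4.17e-19). Tcf15, a factor of quiescent stem cells, rose by 1.97. Of 39 interferon genes 29 rose and Gbp3 fell (33 and 2 adjusted over the list alone, median 0.87, adjusted p = 8.69e-21), with the interferon brake Usp18 up by 1.83 and Ifi44 by 2.77. Of 26 megakaryocyte-erythroid genes 19 rose (21 up and 1 down adjusted over the list alone, median 0.91, adjusted p = 6.46e-13). Car2, a carbonic anhydrase, rose by 1.04 ± 0.11, from 214 ± 12.6 to 441 ± 34.3 CPM, and the transcription factor Gfi1b by 0.89. Of 25 myeloid progenitor genes 10 fell (14 adjusted over the list alone, median -0.61, adjusted p = 1.31e-11). Of 36 genes of G2 and mitosis 15 fell (20 adjusted over the list alone, median -0.27, adjusted p = 1.08e-05), with Aurkb, a mitotic kinase, down by 0.54 and Cdca3 by 0.53. With an estimated correlation the adjusted p was 0.509 for mitosis and 0.483 for the other lists.

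Markers of mature cells moved with these groups. Of 19 mast cell and basophil genes 9 fell and Prss34, a basophil protease, rose (2 up and 10 down adjusted over the list alone, median -0.81, adjusted p = 6.65e-07, and adjusted p = 0.483 with an estimated correlation); Gzmb fell by 2.38. Without the clusters of mature cells, which hold the mast-like cells, the list no longer passed (adjusted p = 0.869), Fcer1a stood at -0.27 and Gzmb at -0.91, and Cma1 turned to 0.41. Of 13 genes of mature B and plasma cells 5 rose (6 adjusted over the list alone, median 1.31, adjusted p = 0.00626, and adjusted p = 0.525 with an estimated correlation), a call that ended without vehicle replicate 3 (adjusted p = 0.0626) or nilotinib replicate 3 (0.109). In STAT5 and cytokine feedback 2 of 15 genes rose and 4 fell: Id1 fell by 2.69 ± 0.17, from 23.9 ± 3.62 to 3.68 ± 0.364 CPM, and Socs3 by 1.5, while Socs2, another STAT5 target, rose by 1.18 ± 0.18. The list (3 up and 5 down adjusted over the list alone, median -0.39, adjusted p = 0.028, and 0.509 with an estimated correlation) lost its call without vehicle replicate 3, nilotinib replicate 3 or 4, and without mature clusters (0.104).

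In energy metabolism 41 of 75 nuclear-encoded respiratory chain genes fell at 2 weeks and none rose (56 down adjusted over the list alone, median -0.30, adjusted p = 6.38e-14, and adjusted p = 0.502 with an estimated correlation). Uqcrq fell by 0.72 ± 0.09, from 565 ± 13.9 to 343 ± 36.8 CPM (adjusted p = 0.00268), Ndufb8 of complex I by 0.49 and the electron carrier cytochrome c, Cycs, by 0.66. Of 13 mitochondria-encoded genes 2 fell (1 adjusted over the list alone, median -0.24, adjusted p = 0.0207, and adjusted p = 0.525 with an estimated correlation), with mt-Nd1 down by 0.67; that call ended without vehicle replicate 3 (adjusted p = 0.346). In the TCA cycle and pyruvate entry 15 of 25 genes fell and none rose (16 adjusted over the list alone, median -0.33, adjusted p = 5.51e-07, and adjusted p = 0.483 with an estimated correlation), among them Mpc1 of the pyruvate carrier by 0.68. Of 75 mitochondrial ribosome genes 33 fell (38 adjusted over the list alone, median -0.26, adjusted p = 5.9e-11, and adjusted p = 0.509 with an estimated correlation), Mrpl20 by 0.58.

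Of 25 glycolysis genes 11 fell and 3 rose at 2 weeks (15 and 4 adjusted over the list alone, median -0.35, adjusted p = 0.00118, and adjusted p = 0.502 with an estimated correlation). Gapdh fell by 0.76 ± 0.09, from 2894 ± 137 to 1711 ± 88.8 CPM, and Pgk1 by 0.56, while Ldhb, the lactate dehydrogenase subunit of oxidative tissues, rose by 1.04. HIF targets had 6 falls and 3 rises among 29 (the same numbers adjusted over the list alone, median -0.08, adjusted p = 0.0302, and adjusted p = 0.483 with an estimated correlation), with the oxygen sensor Egln3 down by 0.80 and the oxidase Ero1l by 1.10. The HIF call ended without vehicle replicate 3 (adjusted p = 0.154), without nilotinib replicate 4 (0.0582) and without mature clusters (0.0555). Of 18 genes of amino acid transport and glutamine use 7 fell (13 adjusted over the list alone, median -0.58, adjusted p = 1.08e-05, and adjusted p = 0.483 with an estimated correlation), with the transaminase Got1 down by 0.68 and the leucine transporter Slc7a5 by 1.08. In cholesterol synthesis 6 of 22 genes rose and 1 fell (9 and 1 adjusted over the list alone, median 0.33, adjusted p = 0.00489, and 0.554 with an estimated correlation), with Stard4 up by 0.83 and Srebf2 by 0.47. The list lost its call without vehicle replicate 3 or nilotinib replicate 4.

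Kit, Ly6a, Flt3 and Abl1 did not pass at 2 weeks, at 0.32, -0.09, -0.06 and 0.07. Mouse Bcr rose by 0.38 ± 0.09 (adjusted p = 0.022), a call that ended without vehicle replicate 3 (0.37) or 4 (0.40) and nilotinib replicate 3 (0.30). Vehicle replicate 3 stood apart, with 1637 cells and a median of 23456 UMIs per cell. The gene count was 1462 without it, 928 without nilotinib replicate 3, 365 with each cell thinned to 2000 UMIs, 1293 with only these 2 groups in the fit, and 3177 in DESeq2.

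**Figure D1:**
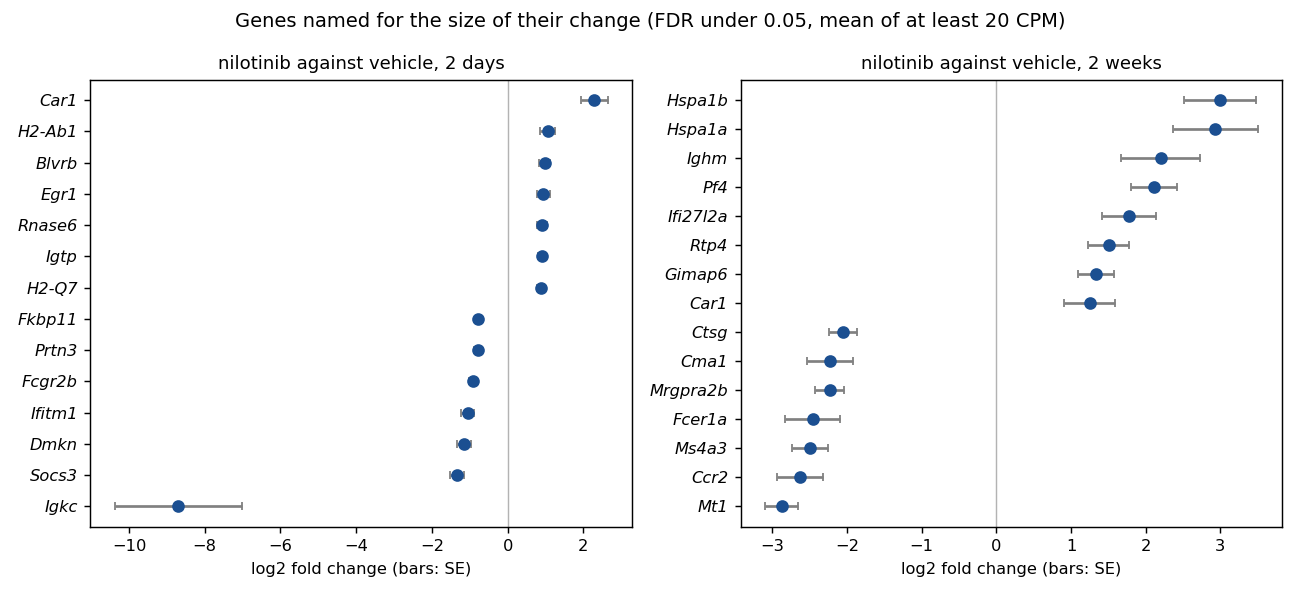
Log2 fold change (x axis, with SE bars from edgeR) of the genes named for the size of their change, with a mean of at least 20 CPM, for nilotinib against vehicle at 2 days and 2 weeks, n = 2 libraries per group, with Ighg1 left out since it has almost no counts with nilotinib. Of those drawn Car1 is highest at 2 days (2.29) and Hspa1b at 2 weeks (3.0), and Mt1 is lowest of those drawn at 2 weeks (-2.88).

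The 2-day and 2-week changes overlapped. Of the 114 genes that rose at 2 days 90 also rose at 2 weeks (13.3 expected of independent lists), and of the 67 that fell 61 fell again (7.66 expected); 2 went opposite ways. Among genes named at both times Car1, Gbp2, Iigp1, Mllt3, Srebf2 and Stard4 had positive values at each, and Socs3, Id1, Prtn3, Gapdh, Cdca3 and Uqcrq negative ones. The test of the difference itself, which treats the change at 2 weeks minus that at 2 days, called 4 genes, Calca, Cx3cr1, Slc4a8 and Ppic, named after their values were seen.

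Cells were grouped into clusters and named by fixed marker lists, and the shares of the classes differed between groups by varying amounts. Stem-cell-like (HSC-like) cells made up 32.6% ± 1.03 with nilotinib and 29.3% ± 0.518 with vehicle at 2 days (SD, n = 2; exact permutation test, two-sided, p = 0.333, the smallest that 2 against 2 allows). At 2 weeks they were 34.1% ± 4.62 with nilotinib and 15.6% ± 17.0 with vehicle, where replicate 3 had 3.54% and replicate 4 27.6%; the difference of 18.5 was 6.50 without vehicle replicate 3. Myeloid-like cells were 12.3% ± 0.982 against 19.8% ± 1.68 at 2 days and 2.41% ± 0.147 against 10.4% ± 4.09 at 2 weeks. Megakaryocyte-erythroid-like cells were 12.6% ± 0.519 against 7.90% ± 0.213 at 2 days and 9.63% ± 2.34 against 6.46% ± 0.882 at 2 weeks. Cells in G2 and mitosis clusters were 9.85% ± 0.288 against 15.4% ± 1.28 at 2 days, and 15.9% ± 4.76 against 10.7% ± 13.2 at 2 weeks. S phase clusters were 14.6% against 14.3% at 2 days and 20.2% ± 2.81 against 8.46% ± 11.7 at 2 weeks. Vehicle replicate 3 had 1.34% and 0.183% of its cells in these 2 classes and replicate 4 20% and 16.7%. Clusters rest on the same genes as the tests, so shares and gene values are not independent. The HSC-like difference at 2 days was 0.847 at the finer clustering and 9.78 without centring of libraries.

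**Figure D2:**
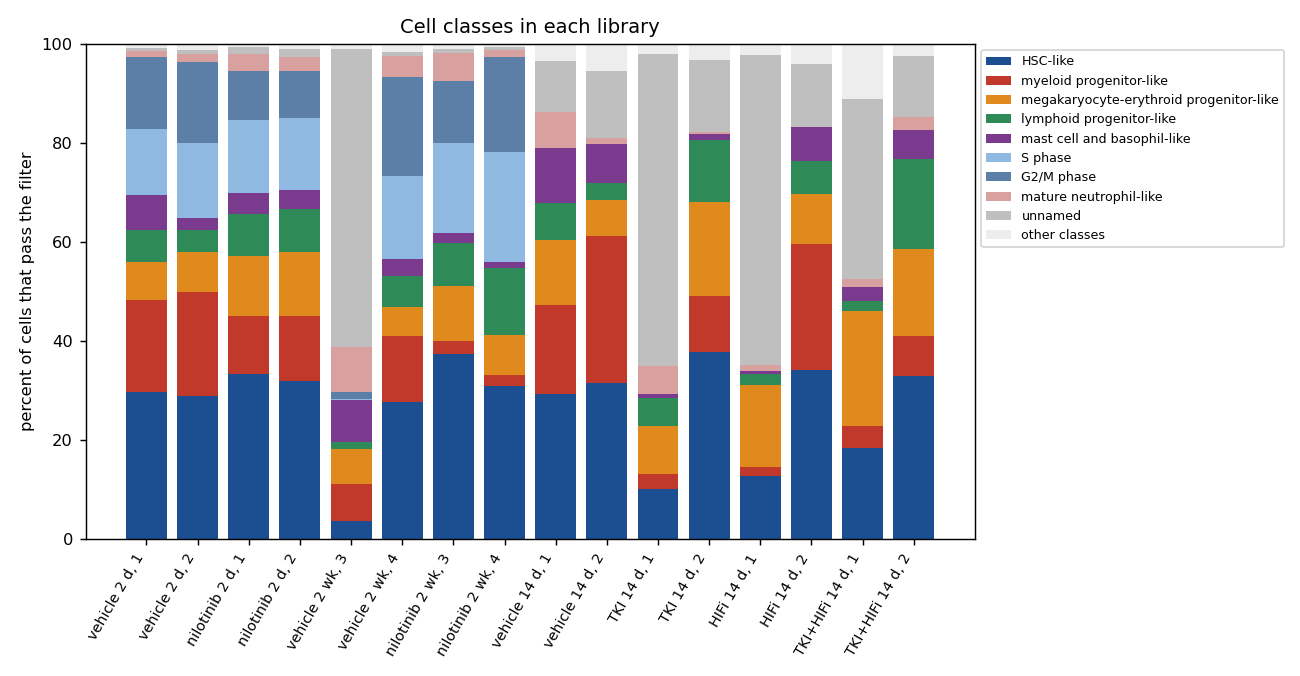
Percent of cells in each class (y axis) in each of the 16 libraries. HSC-like cells with nilotinib at 2 weeks averaged 34.1%, and vehicle replicate 3 at 2 weeks stands at 3.54% with 60.4% of its cells in unnamed clusters.

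HSC-like cells were also tested alone. At 2 days 84 genes changed there (45 up, 39 down), and at 2 weeks 97 (35 up, 62 down). Socs3 fell at both times, by 1.67 ± 0.18 (SE) and 1.82 ± 0.21 on the log2 scale, and Id1 by 1.37 and 2.55. Iigp1 rose by 2.14 and 1.23. H2-Aa, a class II gene, rose by 2.35 at 2 days, and Ccnb2 fell by 1.02. At 2 weeks Mt1 fell by 2.27 and Ctsg by 1.72, and Procr, a surface marker of stem cells, rose by 0.72 ± 0.14 (adjusted p = 0.028), as did Mllt3 by 0.84. Genes named for HSC-like cells outside the other comparisons' rule were chosen after their values were seen. Procr and Ccnb2 are top genes of the HSC-like clusters, which stem cell genes name. Values of these genes there are not independent of that naming.

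Lists in HSC-like cells showed lower values for cell division at both times: G2 and mitosis at -0.57 (adjusted p = 4.38e-20) and -0.45 (2.81e-11), and DNA replication at -0.44 (5.1e-23) and -0.49 (1.21e-14). With an estimated correlation neither passed (adjusted p = 0.308 and 0.56 for mitosis, 0.392 and 0.64 for replication). Over all cells replication stood at -0.17 and -0.16. Cycling cells form classes of their own, so these lists do not show that stem cells divide less. Interferon genes were higher, at 0.32 (7.08e-19) and 0.42 (1.21e-14), and adjusted p = 0.291 and 0.328 with an estimated correlation. Stem cell genes were higher, at 0.18 (0.0147) and 0.40 (8.09e-06), and adjusted p = 0.613 and 0.679 with an estimated correlation; at 2 days they stood at -0.053 in clusters made without centring of libraries (0.582) and did not pass in the larger HSC-like cluster alone (0.13; 0.0579). The nuclear-encoded respiratory chain was lower at 2 days, at -0.18 (2.32e-13, and adjusted p = 0.502 with an estimated correlation), and did not pass at 2 weeks, at -0.055 (adjusted p = 0.495). Without vehicle replicate 3 it stood at -0.16 at 2 weeks (5.16e-09), and in HSC-like cells from clusters made without centring of libraries at -0.061 (0.0493), with adjusted p = 0.765 and 0.798 with an estimated correlation. The mitochondria-encoded genes passed at 2 weeks, at -0.11 (0.00722, and adjusted p = 0.679 with an estimated correlation), but not without vehicle replicate 3 (0.801). TCA genes stood at -0.17 (2.65e-05) and -0.084 (0.41), and at 2 weeks without vehicle replicate 3 at -0.15 (0.00965), with adjusted p = 0.468 at 2 days and 0.765 without that library with an estimated correlation. HIF targets stood at -0.03 and 0.00. Glycolysis did not pass, with a median of 0.10 at 2 days against a test direction of down (0.943) and -0.05 at 2 weeks (0.291). The class joins 2 clusters, the smaller with leading genes of a G2 and mitosis cluster at resolution 1.0. The smaller, led by histone genes and Ccnb2, was 15.9% and 19.1% of HSC-like cells with vehicle at 2 days, against 10.2% and 9.81% with nilotinib, and 5.17% and 14.7% against 10.7% and 16.8% at 2 weeks. In the larger cluster alone mitosis genes stood at -0.46 (8.5e-11) and -0.40 (1.24e-08) and replication at -0.49 (1.5e-29) and -0.50 (2.33e-14), with adjusted p = 0.379, 0.58, 0.358 and 0.58 with an estimated correlation. In the cells outside HSC-like clusters the respiratory chain stood at -0.21 at 2 days (9.28e-13) and -0.25 at 2 weeks (1.13e-10), with adjusted p = 0.452 and 0.52 with an estimated correlation. Without single libraries of its own groups the HSC-like gene count at 2 days was 13 (without nilotinib replicate 1), 54 (vehicle replicate 1), 19 (vehicle replicate 2) and 29 (nilotinib replicate 2). Without vehicle replicate 3 of 2 weeks, which shares the estimate of spread, it was 240. At 2 weeks it was 36 without vehicle replicate 4, 178 without vehicle replicate 3 and 253 without nilotinib replicate 4, and 325 in clusters made without centring (84 without vehicle replicate 3).

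The 2 experiments can be set side by side for nilotinib at 2 weeks and TKI at 14 days, which have separate vehicle libraries. Stem cell, interferon and megakaryocyte-erythroid genes had higher medians in both and respiratory chain, TCA, mitochondrial ribosome and mast cell genes lower ones. Across 14085 genes the log2 changes correlated with r = 0.560 and rho = 0.589; genes are not independent replicates, so no p is given. Of 1661 genes that rose at 2 weeks 89.0% were higher with TKI, against 48.5% of all genes, and of 1634 that fell 90.0% were lower. Of genes of at least 20 CPM in both experiments 30.1% were higher. There it was 86.6% of 411 that rose, and 93.5% of 1053 that fell were lower. Lower lists of abundant genes share that background. Leaving out single libraries gave r from 0.402 (without vehicle replicate 2 of the 14-day experiment) to 0.551.

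**Figure D3:**
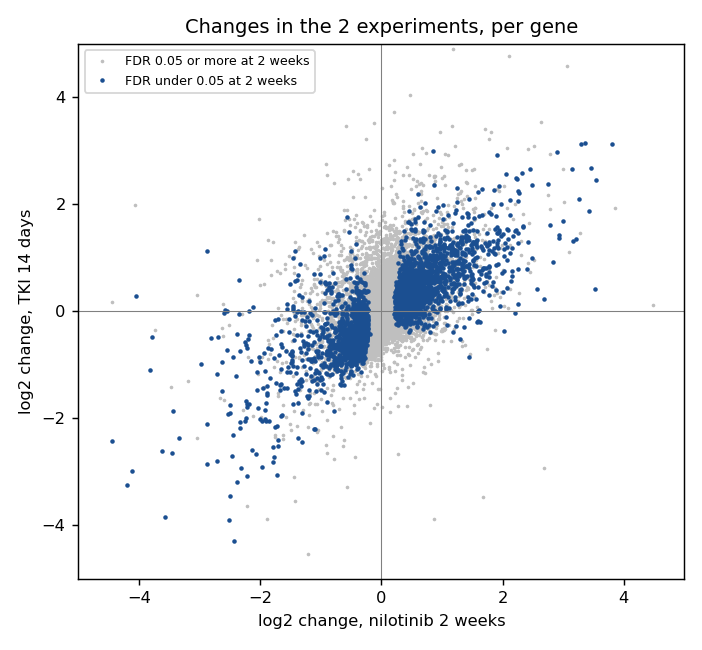
Log2 change per gene for nilotinib at 2 weeks (x axis) and TKI at 14 days (y axis), with genes changed at 2 weeks in blue and 15 genes beyond a log2 change of 5 not drawn. Pearson's r across genes is 0.560.

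TKI against vehicle at 14 days repeats the question in the second experiment. Stem cell genes were higher with TKI (median log2 1.02), as were interferon (0.89) and megakaryocyte-erythroid genes (0.98), while the respiratory chain (-0.57), mitochondrial ribosome (-0.66) and TCA cycle (-0.42) were lower. No single gene passed in edgeR at 14 days, with 0 called for TKI (1023 at an unadjusted p under 0.05; 61 in DESeq2; 602 in edgeR with each hashtag as a sample; 0 in limma voom with the library as a block). The spread between libraries was larger than in the time course, with a common dispersion of 0.133 against 0.0132, and 1% of genes changed 2-fold in simulated data were found. Gimap6 was higher by 1.76 ± 0.23 (SE), at 134 ± 18.1 against 39.5 ± 1.34 CPM (SD, n = 2; edgeR adjusted p = 0.74).

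Of 30 stem cell genes 28 were higher with TKI (2 up adjusted over the list alone, adjusted p = 6.11e-15, and adjusted p = 0.448 with an estimated correlation), including Clec1a at 1.90 and Procr at 1.06. Interferon genes (33 of 38 higher; 2 up adjusted over the list alone, adjusted p = 1.4e-10, and adjusted p = 0.331 with an estimated correlation) included Irf7, a driver of interferon production, at 1.40 ± 0.29 and Iigp1 at 2.50. The megakaryocyte-erythroid list (24 of 26 higher, adjusted p = 1.29e-07, and adjusted p = 0.497 with an estimated correlation) had Car2 at 1.53 ± 0.32, with 306 ± 35.7 against 106 ± 12 CPM; its call ended without vehicle replicate 2 (adjusted p = 0.0558) or TKI replicate 2 (0.391). Haemoglobin and other mature red-cell genes were higher in 10 of 11 (5 up adjusted over the list alone, median 1.24, adjusted p = 4.02e-13, and adjusted p = 0.333 with an estimated correlation), with Hba-a2 at 12.1 ± 2.76 against 0.193 ± 0.199 CPM. Myeloid progenitor genes were lower (median -0.69; 21 of 25, adjusted p = 5.48e-06, and adjusted p = 0.497 with an estimated correlation), with the antibody receptor Fcgr3 at -1.25. Mast cell genes were lower (median -0.84; 4 down adjusted over the list alone, adjusted p = 4.66e-07, and adjusted p = 0.448 with an estimated correlation), with Gzmb at -3.19; without mature clusters the list did not pass (adjusted p = 0.161).

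The nuclear-encoded respiratory chain was lower in 75 of 76 genes with TKI (adjusted p = 2.63e-15, and adjusted p = 0.497 with an estimated correlation), with Atp5k of ATP synthase at -0.93 ± 0.31, 228 ± 26.1 against 435 ± 12.5 CPM. No member passed in edgeR, also adjusted over the list alone, or in DESeq2, and 7 were lower at an unadjusted p under 0.05. By replicate number the medians were -0.75 and -0.49, and for the crossed pairs -1.19 and 0.03. All 75 mitochondrial ribosome genes were lower (adjusted p = 9.12e-18, and adjusted p = 0.497 with an estimated correlation), Mrps5 at -0.97. TCA genes were lower in 23 of 25 (adjusted p = 3.21e-05, and adjusted p = 0.499 with an estimated correlation), the cytosolic member Idh1 at -1.07, but not without TKI replicate 1 (adjusted p = 0.123). Glycolysis had a median of -0.26 (adjusted p = 0.0345, and 0.497 with an estimated correlation), Eno1 at -1.18, and passed neither without vehicle replicate 2 nor TKI replicate 1 or 2. The mitochondria-encoded genes had a median of 0.01 and a mean of -0.02 (adjusted p = 0.72), and HIF targets a median of -0.15 (0.119; 0.0342 without vehicle replicate 1), with Ero1l at -1.15. Mitosis genes stood at -0.40 (2.7e-06, and adjusted p = 0.497 with an estimated correlation; 0.0765 without TKI replicate 1), Tacc3 at -0.67.

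Genes that respond to cell handling stood with these groups. Immediate early and dissociation-stress genes had a median of 1.5 with TKI (adjusted p = 5.51e-05, and adjusted p = 0.554 with an estimated correlation), with Egr1 at 2.70 ± 1.58. The call ended without vehicle replicate 1 (adjusted p = 0.264), and without TKI replicate 1 the direction turned (0.949). The unnumbered libraries of the 3 treated groups had 1.83% to 2.34% of counts in Gm42418, against 0.198% to 0.546% in the other 5, and a term for this split took the stress list to an adjusted p of 0.762, left the respiratory chain past the threshold (7.84e-08) and brought the mitochondria-encoded list (1.83e-05) and HIF targets (0.0445) past it. Kit, Ly6a, Flt3, Bcr and Abl1 stood at -0.02, -0.11, 0.85, 0.43 and 0.33.

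HIFi was also compared with vehicle at 14 days. Stem cell genes (median 0.62), ERK feedback genes (1.09) and interferon genes (0.36) were higher, and neutrophil granule genes (-2.15), myeloid progenitor genes (-0.61) and mitosis genes (-0.43) lower. HIF targets were not different as a list (30 measured, median -0.03, mean 0.04, test direction down, adjusted p = 0.961). edgeR called 0 genes (546 at an unadjusted p under 0.05; 13 in DESeq2; 2 with each hashtag as a sample; 0 in limma voom). Among HIF targets Ero1l stood at -0.78 ± 0.31 and Ddit4, a brake on mTOR, at 1.06 ± 0.52 (edgeR adjusted p = 0.98).

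All 18 ERK feedback genes were higher with HIFi (adjusted p = 1.8e-08), among them the phosphatases Dusp4 at 1.44 and Dusp6 at 1.06. The list stood at 1.86 between the unnumbered libraries and 0.22 between the second ones (1.04 and 0.92 for the crossed pairs), and its adjusted p was 0.00263 without HIFi replicate 1 and 5.47e-08 with the replicate block. All 36 mitosis genes were lower (5.27e-12), with Anln at -0.63 and Tpx2 at -0.64. All 17 neutrophil genes were lower (1.34e-12), Wfdc21 at 32.3 ± 7.69 against 153 ± 79.2 CPM and Chil3 at -2.82. The neutrophil list stood at -2.30 between the unnumbered libraries and -2.48 between the second ones, at -0.078 for unnumbered HIFi against second vehicle and at -4.59 for the other crossed pair. Neutrophil-like cells were 7.33% and 1.35% of the vehicle libraries and 1.18% and 0.0803% of the HIFi ones. Without mature clusters the list stood at -1.81 (9.38e-12), and its adjusted p was 0.000155 without vehicle replicate 1 and 0.00025 without HIFi replicate 2. Myeloid progenitor genes were lower in 24 of 25 (3.1e-11), Ly6c2 at -1.64. Interferon genes (4.98e-08) had Irf7 at 1.17, and stem cell genes (4.66e-09) had Procr at 0.80 and Esam at 0.88. With an estimated correlation the adjusted p was 0.508 for interferon genes and 0.648 for the other lists here.

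For energy metabolism with HIFi the respiratory chain had a median of -0.17 (70 of 76 lower, adjusted p = 0.00122, and adjusted p = 0.97 with an estimated correlation), with Atp5k at -0.54. That call ended without vehicle replicate 2 (adjusted p = 0.89), the direction turned without HIFi replicate 1 (0.00167) and it turned with the Gm42418 term (0.782). Glycolysis (median -0.11, adjusted p = 0.464), the TCA cycle (-0.10; 0.076) and the mitochondria-encoded genes (-0.06; 0.364) did not pass. Without vehicle replicate 1 glycolysis and TCA genes passed, TCA genes also without HIFi replicate 2 and with the replicate block (0.036), and the mitochondria-encoded list without HIFi replicate 1. Slc2a1, the glucose transporter, stood at 0.61. Stress genes were higher here too (median 1.61, adjusted p = 1.8e-08, and adjusted p = 0.759 with an estimated correlation), at 4.13 between the unnumbered libraries and -0.11 between the second ones (1.46 and 2.21 for the crossed pairs), and with 0.000639 without HIFi replicate 1. Kit, Ly6a, Flt3, Bcr and Abl1 stood at -0.20, 0.39, 0.50, 0.09 and 0.19.

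TKI with HIFi against vehicle shows what the combination does. Stem cell genes (median 0.92), megakaryocyte-erythroid genes (1.09), mature red-cell genes (1.29) and interferon genes (0.65) were higher, and the respiratory chain (-0.39), mitochondrial ribosome (-0.49) and myeloid progenitor genes (-0.76) lower. edgeR called 0 genes (784 at an unadjusted p under 0.05; 24 in DESeq2; 251 with each hashtag as a sample; 0 in limma voom). Fgd5, a gene of stem cells, stood at 1.63 ± 0.44 and Car2 at 1.44 ± 0.32, with 287 ± 61.4 against 106 ± 12 CPM (SD, n = 2; edgeR adjusted p = 0.94).

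In the combination 27 of 30 stem cell genes were higher (1 up adjusted over the list alone, adjusted p = 5.37e-19, and adjusted p = 0.287 with an estimated correlation), with Clec1a at 1.82 and Procr at 0.90. Of 26 megakaryocyte-erythroid genes 25 were higher (3.4e-20, and adjusted p = 0.287 with an estimated correlation), with Klf1 at 2.13 and the water channel Aqp1 at 2.27. All 11 mature red-cell genes were higher (6 up adjusted over the list alone; 1.91e-24, and adjusted p = 0.124 with an estimated correlation). Interferon genes (33 of 38 higher; 3.08e-10, and adjusted p = 0.124 with an estimated correlation) had Irgm1 at 0.60 and Iigp1 at 1.85. Myeloid progenitor genes (23 of 25 lower; 8.43e-12, and adjusted p = 0.468 with an estimated correlation) had the growth factor receptor Csf1r at -1.23 ± 0.31.

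The respiratory chain was lower in 75 of 76 genes in the combination (adjusted p = 1.36e-07, and adjusted p = 0.727 with an estimated correlation), with Atp5k at -0.62. It did not pass without vehicle replicate 2 (0.054) or with the Gm42418 term (0.319). All 75 mitochondrial ribosome genes were lower (4.37e-10, and adjusted p = 0.727 with an estimated correlation; 0.16 with the Gm42418 term), Mrps5 at -0.78. TCA genes (median -0.28; 0.00689, and adjusted p = 0.727 with an estimated correlation) had the cytosolic member Idh1 at -0.88, and glycolysis (-0.32; 0.0106, and adjusted p = 0.468 with an estimated correlation) had Eno1 at -1.09. Both calls ended without vehicle replicate 2 or combination replicate 2, and the TCA call with the Gm42418 term (0.444). HIF targets were lower (median -0.23; 0.0389, and adjusted p = 0.568 with an estimated correlation), with Ero1l at 33.4 ± 0.844 against 67.4 ± 9.03 CPM and the HIF-induced demethylase Kdm3a at 0.40. That call ended without vehicle replicate 2, combination replicate 1 or 2, with thinned cells (0.0551) and without mature clusters (0.0831). The mitochondria-encoded list had a median of 0.06 (0.926), and a negative direction without combination replicate 1 (0.0395) and with the Gm42418 term (7.55e-05). Stress genes had a median of 0.80 (0.012, and adjusted p = 0.746 with an estimated correlation), 0.189 with the replicate block; without vehicle replicate 1 (0.597) or combination replicate 1 (0.0162), and with the Gm42418 term (0.00737), they turned. Kit, Ly6a, Flt3, Bcr and Abl1 stood at 0.02, -0.02, 0.27, 0.10 and 0.36.

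TKI with HIFi against TKI alone asks what HIFi adds to the kinase inhibitor. Genes of antigen presentation (median -1.46), of mature B cells (-1.34) and of T and NK cells (-1.65) were lower with HIFi added, and genes of mitosis (0.28), the respiratory chain (0.18) and the mitochondrial ribosome (0.17) slightly higher. HIF targets (15 higher and 15 lower of 30, adjusted p = 0.677) and glycolysis (median -0.01; 0.801) did not differ as lists. edgeR called 0 genes (184 at an unadjusted p under 0.05; 0 in DESeq2; 0 with each hashtag as a sample; 0 in limma voom). H2-DMb1, a class II chaperone, stood at -0.87 ± 0.22 and Trbc2, a T cell receptor chain, at -3.27 ± 0.73 (edgeR adjusted p = 1).

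All 7 class II genes were lower with HIFi added (1 down adjusted over the list alone, adjusted p = 1.07e-08, and adjusted p = 0.318 with an estimated correlation), H2-Ab1 at -1.28. All 12 mature B cell genes were lower (3.97e-10, and adjusted p = 0.318 with an estimated correlation; 0.0658 without combination replicate 1), Jchain at -3.07. T and NK cell genes were lower in 14 of 15 (1 down adjusted over the list alone; 4.04e-14, and adjusted p = 0.318 with an estimated correlation), Cd3g at -3.15. Against TKI replicate 1 the 2 combination libraries stood at -1.96 and -1.98 for class II and -2.03 and -2.25 for T and NK cell genes, and against TKI replicate 2 at -0.68 and -0.77, and -0.49 and -0.44. Without TKI replicate 1 these lists had 0.000871 and 0.000281. The mature B list stood at -3.16 between the unnumbered libraries and 0.17 between the second ones (-0.93 and -1.15 for the crossed pairs), with 4.46e-12 under the replicate block. All 36 mitosis genes were higher (1.04e-13, and adjusted p = 0.635 with an estimated correlation), Gtse1 at 0.60 and Ckap2 at 0.36, but did not pass without TKI replicate 1 (0.0674). The respiratory chain was higher in 73 of 76 genes (1.04e-07, and adjusted p = 0.709 with an estimated correlation), Uqcr11 at 0.37, and the mitochondrial ribosome in 73 of 75 (2.31e-07, and adjusted p = 0.709 with an estimated correlation). Without TKI replicate 1 the direction of both turned (0.0393 and 0.000871). TCA genes (median 0.13; 0.0109, and adjusted p = 0.709 with an estimated correlation) lost the call without combination replicate 1 (0.193) and with thinned cells (0.391), and turned without TKI replicate 1 (0.23). The mitochondria-encoded list did not pass (0.05; 0.555), though it did without TKI replicate 1 (0.0252) or combination replicate 2 (0.00341). Stress genes stood at -0.64 (0.00451, and adjusted p = 0.709 with an estimated correlation), turning without TKI replicate 1 (0.00185) or combination replicate 2 (0.0327). Kit, Ly6a, Flt3, Bcr and Abl1 stood at 0.03, 0.08, -0.58, -0.34 and 0.04.

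**Figure D4:**
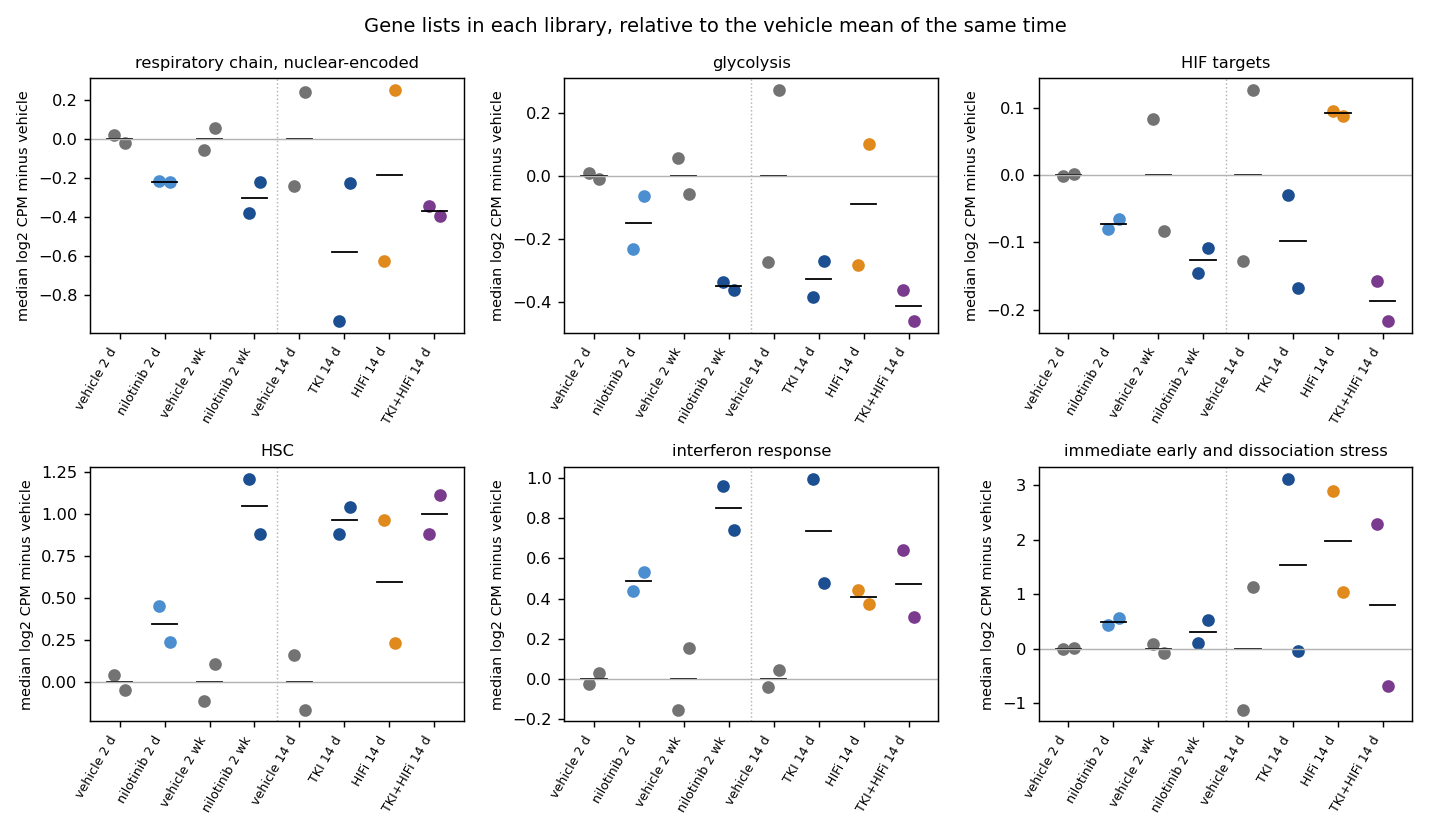
Median log2 level of gene lists in each of the 16 libraries, minus the mean of the matched vehicle libraries. Stem cell genes were higher in the comparisons with nilotinib at 2 weeks (median change 1.01) and TKI at 14 days (1.02), and the respiratory chain lower (-0.30 and -0.57).

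Class shares at 14 days varied widely between libraries of a group. HSC-like cells were 30.3% ± 1.56 with vehicle, 23.8% ± 19.5 with TKI, 23.4% ± 15.1 with HIFi and 25.6% ± 10.4 with both (SD, n = 2). In clusters made without centring they were 10.7%, 9.56%, 4.70% and 14.8%. The differences from vehicle of -6.46, -6.92 and -4.71 points turned to 7.36, 3.73 and 2.61 without replicate 1 of TKI, of HIFi and of both, and that of both turned to 4.09 without centring. Unnamed clusters took 11.9% ± 2.20, 38.8% ± 34.3, 37.7% ± 35.4 and 24.3% ± 17.0. Mast-like cells were 9.41% ± 2.28 with vehicle and 1.02% ± 0.255 with TKI, and myeloid-like cells 24.0% ± 8.29 and 7.28% ± 5.99. With each hashtag as a sample, which are not independent libraries, HSC-like shares gave exact permutation p = 0.429 for TKI, 0.371 for HIFi, 0.314 for both against vehicle and 0.971 for both against TKI. Within HSC-like cells edgeR called 0 genes for TKI and 0 for both against TKI, and 156 and 24 with no filter on low counts; the respiratory chain stood at -0.50 (adjusted p = 3.92e-16) and 0.17 (6.94e-06), and adjusted p = 0.571 and 0.84 with an estimated correlation.

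Surface antibodies were counted in the 14-day libraries, and no test was run on them. CD135, almost absent from the unnumbered libraries, is part of the ratio of every antibody and shifts it there, so values compare only within the unnumbered or within the second libraries. CD150, a stem cell marker, had a median centred log ratio of -0.541 and -0.762 in the vehicle libraries, -0.440 and -0.346 with TKI, -0.461 and -0.684 with HIFi, and -0.286 and -0.288 with both. CD48, which long-term stem cells lack, had 3.15 and 3.81 with vehicle, 2.94 and 3.57 with TKI, 3.53 and 3.89 with HIFi, and 2.55 and 3.40 with both. CD34 had 0.153 and 0.0325 with vehicle, 0.0723 and -0.212 with TKI, 0.238 and -0.0516 with HIFi, and 0.446 and -0.220 with both. CD16/32 had 0.606 and -0.102 with vehicle, 0.0459 and -0.103 with TKI, -0.0635 and -0.277 with HIFi, and 0.467 and -0.0109 with both. CD135 had at most 8 counts in the unnumbered libraries and at least 29320 in the others.

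On the mm10 build, Uqcrq (ENSMUSG00000044894) lies on chromosome 11 from 53427922 to 53430831, Socs3 (ENSMUSG00000053113) on chromosome 11 from 117966079 to 117970047, and Gapdh (ENSMUSG00000057666) on chromosome 6 from 125161715 to 125166467. All are annotated as protein-coding, and counts were per gene.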

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

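The tests on centring, on a shared preparation round, on stressed cells and on the cells outside HSC-like clusters were chosen after the result was seen; the other tests on explanations were not.

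Several nilotinib changes differed between 2 weeks and 2 days by the test of the difference itself. In edgeR 4 genes passed, named after their values were seen. The exchanger gene Slc4a8 differed by -1.60 ± 0.09 (SE, log2, adjusted p = 0.000697), a call that held in every alternative run. The neuropeptide gene Calca differed by -4.11 (adjusted p = 0.0145); it stood at 1.68 at 2 days and -2.43 at 2 weeks, and at a difference of 0.66 without clusters of mature cells. The chemokine receptor Cx3cr1 differed by -1.77 and the isomerase Ppic by 0.90 (adjusted p = 0.0486 for both). The number of genes was 1 without vehicle 2-day replicate 1 or 2 or nilotinib 2-day replicate 2, 2 without nilotinib 2-day replicate 1, 79 without vehicle 2-week replicate 4 and 42 without nilotinib 2-week replicate 3. Calca lost its call without vehicle 2-day replicate 1 (-4.09) or 2 (-4.13) or nilotinib 2-day replicate 2 (-3.84). Cx3cr1 lost it without vehicle 2-day replicate 1 (-1.89) or 2 (-1.67), nilotinib 2-day replicate 1 (-1.86) or 2 (-1.77), vehicle 2-week replicate 3 (-1.62) or nilotinib 2-week replicate 4 (-1.85). Ppic lost it without the same libraries (0.96, 0.85, 0.81, 0.92, 0.90 and 0.79).

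The nilotinib change of stem cell genes was higher at 2 weeks than at 2 days (median difference 0.57; 9 up adjusted over the list alone, adjusted p = 9.78e-18, and adjusted p = 0.434 with an estimated correlation). That of myeloid progenitor (-0.58; 1.13e-12) and mast cell genes (-1.38; 4e-24) was lower, with mast cell genes at a median of 0.35 at 2 days and -0.81 at 2 weeks (7 and 10 adjusted over the list alone, adjusted p = 0.434 for each with an estimated correlation). These 3 calls held without any single library. The respiratory chain differed by -0.065 (adjusted p = 0.0266, and 0.88 with an estimated correlation). It was not past the threshold without vehicle 2-day replicate 2, nilotinib 2-day replicate 2 or vehicle 2-week replicate 4, and turned without nilotinib 2-week replicate 3. In HSC-like cells it differed the other way, by 0.15 (1.4e-08, and adjusted p = 0.717 with an estimated correlation), and by 0.025 without vehicle 2-week replicate 3 (0.133). Glycolysis differed by -0.20 (0.034, and adjusted p = 0.714 with an estimated correlation), lost without vehicle 2-day replicate 2 (0.084), nilotinib 2-day replicate 2 (0.411), vehicle 2-week replicate 3 (0.173) or nilotinib 2-week replicate 3 (0.0538). Amino acid transport differed by -0.28 (0.00418, and adjusted p = 0.67 with an estimated correlation), lost without nilotinib 2-day replicate 2 (0.0823) or vehicle 2-week replicate 3 (0.285). Interferon genes differed by 0.22 (0.000727, and adjusted p = 0.714 with an estimated correlation), lost without vehicle 2-week replicate 3 (0.173) or nilotinib 2-week replicate 3 (0.0517). Class II genes differed by -0.64 (0.00628, and adjusted p = 0.67 with an estimated correlation), lost without vehicle 2-day replicate 2 (0.0804), nilotinib 2-day replicate 2 (0.101), vehicle 2-week replicate 4 (0.24) or nilotinib 2-week replicate 4 (0.102). Mature B cell genes differed by 0.92 (0.00258, and adjusted p = 0.67 with an estimated correlation), lost without vehicle 2-day replicate 1 (0.271), vehicle 2-week replicate 3 (0.131) or nilotinib 2-week replicate 3 (0.108).

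At 14 days the lists departed from the sum of the TKI and HIFi changes. The combination was above the sum for the respiratory chain (median 0.35, adjusted p = 1.64e-07), TCA cycle (0.25; 0.0051), mitochondrial ribosome (0.37; 9.23e-08), mitosis genes (0.71; 6.28e-20), myeloid progenitor genes (0.45; 0.00023) and neutrophil genes (1.47; 9.23e-08). It was below the sum for ERK feedback (-1.44; 2.67e-07), interferon (-0.75; 7.35e-07), stress (-2.28; 1.6e-08), class II (-1.18; 0.0207), stem cell (-0.58; 1.15e-05) and T and NK cell genes (-2.22; 5.4e-08). With an estimated correlation these lists had adjusted p = 0.685 to 0.692. No gene passed in edgeR, also with hashtags as samples, or in limma voom (6 in DESeq2). Without HIFi replicate 1 the call ended for the respiratory chain, TCA cycle, mitochondrial ribosome, stem cell and myeloid progenitor genes, and class II turned. Without TKI replicate 1 it ended for the respiratory chain, TCA cycle, mitochondrial ribosome and class II, and without TKI replicate 2 for neutrophil genes. Without vehicle replicate 2 it ended for the TCA cycle and class II, and without combination replicate 1 for these and stem cell genes.

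A lower RNA level of the nuclear-encoded respiratory chain at 2 weeks (median -0.30) may have more than 1 source. Depth per cell and mature cells are argued against as the whole cause, since the list stood at -0.19 with each cell thinned to 2000 UMIs (adjusted p = 3.51e-08) and at -0.35 without mature clusters (2.69e-15). A larger share of HSC-like cells is a candidate for part of it: within HSC-like cells the list stood at -0.055 (0.495), at -0.16 without vehicle replicate 3 (5.16e-09) and at -0.061 in clusters made without centring (0.0493), and these cells had less of this RNA than the others (-0.41). That share alone would give -0.054, and in the cells outside HSC-like clusters the list still stood at -0.25 (1.13e-10). With an estimated correlation neither that list call nor the one in all cells passed (adjusted p = 0.52 and 0.502), so these arguments rest on the medians. Shifts among the other classes, and a response of the cells to nilotinib, stay open and were not tested.

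Vehicle replicate 3 at 2 weeks stood apart, with 1637 cells, 3.54% of them HSC-like and 60.4% in unnamed clusters. The SD over genes of the log2 difference between the vehicle libraries was 0.240, against at most 0.220 in other time-course groups. Without mature clusters it was 0.234 against 0.198, so mature cells are argued against as the whole cause. Thinning (0.301 against 0.23) cannot decide on depth: it left this library 1567 cells, the fewest, and so the most counting error. The low HSC-like share may come from centring each library before clustering: without it the library had 20.7%, and its gap to the mean of the other vehicle libraries went from 25.2 to 5.06 points. No biological explanation was tested, and the labels give none.

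The unnumbered libraries of the 3 treated groups at 14 days stood apart, with 36.3% to 63.0% of cells in unnamed clusters. The second libraries of the same treatments had 12.3% to 14.5%, so treatment alone is argued against. All 4 unnumbered libraries, vehicle included, had at most 8 CD135 antibody counts against at least 29320 in the others, so they shared a part of their preparation. Whether that round, alone or together with treatment, made the 3 stand apart stays open: the vehicle library's deviations correlated at most 0.269 with those of these 3, which correlated at least 0.497 among themselves, but this rests on 1 library. Stressed or damaged cells are a candidate source: immediate early genes were higher in the unnumbered than in the second library by 2.64, 1.53 and 2.97 with TKI, HIFi and both, and lower in vehicle (-2.25).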

How the results depend on the processing

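Runs without clusters of mature cells, with a term for the libraries high in Gm42418, and correlations with single libraries left out were added after the data were seen; the others were set before. Where leaving out a library left 1 in a group, it is assumed to vary like the other groups. Unless a cause is given, the cause was not tested. Each setting chosen before the data were seen ran, except that hashtags exist only in the 14-day experiment, and too few doublets were called for leaving them out to test much, and the replicate block was not run for vehicle over time, where the numbers differ between the times.

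Counts of changed genes moved most. Nilotinib at 2 days (181) gave 933 in DESeq2, 620 with no filter on low counts, 527 with the replicate block, 51 with thinned cells, 451 without mature clusters, 1064 with only 2 groups, and 0 to 1 without single libraries. Nilotinib at 2 weeks (3324) gave 365 with thinned cells, 1293 with only 2 groups, and 928 to 2668 without single libraries. The difference between the times (4) gave 133 in DESeq2, 109 with no filter, 2 without the cell filter, 85 with the block, 8 with thinned cells, 27 without mature clusters and 1 to 79 without single libraries. Vehicle over time (30) gave 313 in DESeq2, 291 with no filter, 9 thinned, 75 without mature clusters, 12 with only 2 groups and 0 to 108. Fewer molecules per cell remain after thinning, and fewer samples with a library left out.

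At 14 days edgeR called 0 genes in each comparison (1023, 546, 784, 184 and 428 at an unadjusted p under 0.05 for TKI, HIFi, both, both against TKI and departure from the sum). DESeq2 gave 61, 13, 24, 0 and 6. Hashtags as samples gave 602, 2 and 251 for TKI, HIFi and both in edgeR, and 0 in limma voom. With no filter both against vehicle gave 1, and single libraries gave 0 to 1 for TKI and for both against TKI. In HSC-like cells nilotinib at 2 days (84) gave 637 with no filter, 1065 with the block, 13 to 54 without single libraries of its groups and 240 without vehicle replicate 3 of 2 weeks; at 2 weeks (97) it was 456, 397, 185 at resolution 1.0, where that library had too few such cells and was left out, 325 without centring (84 without that library too) and 36 to 253. TKI gave 156 and both against TKI 24 with no filter.

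With an estimated correlation every list lost its call. For nilotinib at 2 days the adjusted p was 0.431 for the respiratory chain, 0.443 for glycolysis and 0.417 for the TCA cycle; at 2 weeks 0.502, 0.502 and 0.483, with 0.525 for the mitochondria-encoded genes and 0.483 for HIF targets; for the difference between the times 0.88 for the respiratory chain and 0.714 for glycolysis. For TKI the values were 0.497, 0.497 and 0.499, for HIFi 0.97 for the respiratory chain, for both against vehicle 0.727, 0.468 and 0.727 with 0.568 for HIF targets, for both against TKI 0.709 for the respiratory chain and TCA cycle, and for departure from the sum 0.686 and 0.692.

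Thinned cells gave glycolysis 0.0969 at 2 days, the difference between the times 0.467 for the respiratory chain, turned, and 0.134 for glycolysis, HIF targets 0.0551 in the combination, and TCA genes 0.391 for both against TKI and 0.155 for departure from the sum. Without mature clusters HIF targets passed at 2 days (0.0286), not at 2 weeks (0.0555) or in the combination (0.0831), and TCA genes passed for HIFi (0.030). Calca turned to 0.66 and Cma1 to 0.41. The replicate block brought HIF targets at 2 days (0.0369) and TCA genes for HIFi (0.036) past the threshold. The Gm42418 term brought the mitochondria-encoded genes (1.83e-05) and HIF targets (0.0445) with TKI past it and the mitochondria-encoded genes with HIFi (7.67e-10); the respiratory chain turned with HIFi (0.782) and lost its call in the combination (0.319), as did TCA genes (0.444, and 0.0836 for departure from the sum), and in the combination the mitochondria-encoded genes (7.55e-05) and stress genes (0.00737) turned.

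Adjusted p over runs without single libraries ranged as follows. Nilotinib at 2 days: mitochondria-encoded 0.0384 to 0.212, glycolysis 0.00188 to 0.346, HIF targets 0.0266 to 0.0546. At 2 weeks: mitochondria-encoded 6.14e-05 to 0.346, HIF targets 0.00642 to 0.154. Difference between the times: respiratory chain 3.95e-08 to 0.969. TKI: glycolysis 0.00394 to 0.334, TCA 1.26e-06 to 0.123, HIF targets 0.0342 to 0.647, stress 2.52e-15 to 0.949. HIFi: respiratory chain 1.26e-12 to 0.89, mitochondria-encoded 6.22e-07 to 0.961, glycolysis 0.0382 to 0.842, TCA 0.000175 to 0.997. Both against vehicle: respiratory chain 1.18e-09 to 0.054, mitochondria-encoded 0.0395 to 0.464, glycolysis 0.00197 to 0.297, TCA 0.00032 to 0.532, HIF targets 0.0123 to 0.481, stress 9.44e-13 to 0.597. Both against TKI: respiratory chain 1.07e-14 to 0.0393, mitochondria-encoded 0.00341 to 0.514, TCA 4.34e-05 to 0.23, mitochondrial ribosome 2.82e-18 to 0.00244, stress 6.65e-12 to 0.0327. Departure from the sum: class II 2.75e-05 to 0.494.

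The HSC-like share at 2 days differed by 0.847 points at resolution 1.0 and 9.78 without centring, and that of the combination turned from -4.71 to 4.09 points without centring. The correlation of the experiments was 0.402 to 0.551 without single libraries. Of the main lists 223 values kept direction and side of the threshold, 43 lost the call, 18 gained it and 6 turned; of the other lists 671 kept it, 137 lost it, 5 gained it and 10 turned. With the spread of the 14-day libraries 1% of simulated 2-fold changes were found.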

Other observations

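The histone genes below were chosen as a group after the values were seen; the comparison of the vehicle groups was planned.

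Vehicle cells at 2 weeks differed from vehicle cells at 2 days, which describes the untreated leukaemia over time. Some histone genes, neutrophil granule genes and ERK feedback genes were higher at 2 weeks, and cholesterol synthesis and myeloid progenitor genes lower. In edgeR 30 genes differed, 26 up and 4 down. Of the 26 that rose 14 were histone genes, of 62 histone genes among the 14404 tested, with a median log2 difference of 1.30 over these 14; histone genes were not tested as a group. Hist1h4d, a histone H4 gene, went from 21.1 and 18.8 CPM in the 2-day libraries to 99.4 and 74.0. A cluster led by such genes held 59.9% of the cells of 2-week replicate 3 and none of the other libraries, so that library, which stood apart, moves with this result. The same 14 genes were higher in nilotinib libraries at 2 weeks than at 2 days, by a median of 1.01. Idh1, which supplies NADPH in the cytosol, fell by 0.81 ± 0.09 (SE, log2, adjusted p = 0.0228) and Fkbp11 by 0.63. These genes were named after their values were seen. Time and the round of preparation, libraries 1 and 2 against 3 and 4, cannot be told apart here. The count was 0 without 2-day replicate 1 or 2, 6 without 2-week replicate 3 and 108 without 2-week replicate 4; without single libraries Hist1h4d lost its call for 2-day replicates 1 (2.20) and 2 (2.04), and Idh1 for these (-0.86 and -0.76) and 2-week replicate 3 (-0.81), as did Fkbp11 (-0.56, -0.69 and -0.55).

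Neutrophil genes were higher at 2 weeks in vehicle (median 1.99, 12 of 17 up adjusted over the list alone, adjusted p = 1.44e-13), with Camp, a granule peptide, at 2.20 ± 0.57. Without clusters of mature cells the list did not pass (0.623). All 18 ERK feedback genes were higher (median 0.47, 5 up likewise, 2.89e-07). All 22 cholesterol synthesis genes were lower (median -0.38, 12 down likewise, 1.76e-09). Myeloid progenitor genes were lower (median -0.44, 7 down likewise, 3.49e-07), with the peroxidase Mpo at -0.82. With an estimated correlation the adjusted p was 0.66 for neutrophil and cholesterol genes and 0.55 for the others.

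The antibody counts held values outside the comparisons. CD201, a stem cell marker also called EPCR, had median centred log ratios of -0.715 and -1.96 in the vehicle libraries, and -0.810 to -0.347 in the unnumbered against -1.95 to -1.92 in the second treated libraries. CD135, almost absent from the unnumbered libraries, enters these ratios. In the unnumbered vehicle library 400 cells carried the first hashtag alone, 7196 the second alone and 3946 neither. The low-count group had a mean log10 count of 2.69 for the second and 1.08 for the first, so some may carry the second. Hashtag runs used these calls.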
